A study of Mus musculus with 12 samples.

How the data were processed

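Bulk RNA-seq libraries of sorted CD8+ T cells from mouse tumours were analysed, 12 libraries in 4 groups of 3. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, and both a TruSeq mRNA kit and a SMARTer ultra low input kit are named. The labels do not state whether libraries kept strand, so overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, HISAT2, StringTie and the mm39 build were used, and their versions, order and the annotation are not given in the sources used here. The deposited table held 56980 genes in 12 columns, all of which belong to these samples.

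The values that the authors deposited are labelled expected_counts and were used in the edgeR model in that form, that is, estimated counts per gene. They were already whole numbers, so rounding changed nothing. Small values peaked at 3, 6, 9, 11 and 14 counts, as steps of 2.69 rounded up would (2.67 to 2.71 described them equally well). The next step, 17, was no peak, with 1795 cells of the table against 1839 at 16 and 1659 at 18. On this basis 1 sequenced fragment was taken to be worth about 2.69 counts. Values of 1 and 2, under 1 step, were also frequent, in 11137 and 9290 cells of the table, so this worth is an estimate and fragments may be counted in part. Library totals lay between 98663008 and 102896605 counts. The floor of 3 fragments is 8.1 counts, or 0.082 CPM, per library. It covers counting error only, since amplified fragments are not independent molecules, and genes with a group mean at or under it are given as CPM levels without a fold change. Gene symbols came from the deposited table, and 11 of the 1542 genes without a symbol were named from a reference table in which 52073 of the identifiers matched. That reference is on another build, and no coordinates were used.

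Counts were analysed with edgeR 4.0.16 in R 4.3.3. TMM factors scaled the libraries, filterByExpr by group kept 20411 genes, and 1 quasi-likelihood model of the 4 group means was fitted over the 12 libraries. The labels state no test, and this design lets the groups share 1 estimate of the spread. Comparisons were asGM1-positive against asGM1-negative cells in each tumour type and in their mean, Flt3L Panc02 against Panc02 tumours in each gate, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Standard errors were taken as the absolute log2 fold change, fitted without edgeR's prior count, divided by the square root of the F statistic. The log2 fold changes given beside them include that prior count, which shrinks those of genes with low counts. CPM values use the TMM-scaled library sizes.

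Gene lists (35, covering T cell programs, T cell identity and handling, and other cell types that the gate could hold) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. With the preset correlation 23, 21, 22, 18, 19 and 21 lists were called in the comparisons in the order above. With an estimated correlation 7, 5, 9, 2, 1 and 0 were. The fry test, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, called 9, 14, 16, 9, 13 and 0. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

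Groups, tests, gene lists, the other settings listed below and the rule for naming genes were fixed before the data were examined. The rule took up to 6 genes per direction with the largest log2 fold change among called genes with a mean of at least 5 CPM and no overlap between the compared groups, leaving out gene models, receptor segments, ribosomal and mitochondrial genes. It added up to 4 called members of each list by p, a panel of 32 genes, and up to 5 genes per direction for the interaction. Granzymes C to F, Klra genes, haemoglobin genes and Trgc segments are close paralogs, and how the counting split reads among them is uncertain. Results on some single genes are not reported here.

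Those settings were DESeq2 1.42.0 size factors, upper quartile factors, no filter and a stricter filter on low counts (5 CPM in 3 libraries), the DESeq2 test, limma-voom with quality weights, a fit to the compared libraries alone, the replicate number as a block, and leaving out each library in turn. Counts divided by the fragment step, a run without both Panc02 libraries numbered 1, and a count without genes of other cell types were chosen after seeing the data. The edgeR and list tests were run on simulated counts with 200 changed genes. Genes were drawn independently of each other there, so the simulation cannot test the preset correlation of the list tests. In the Panc02 gate comparison (19763 genes) edgeR recovered 7.94% of genes changed 1.5-fold, 40% of those changed 2-fold and 64.1% of those changed 4-fold, with 2.25% false calls. In the Flt3L Panc02 gate comparison (19710 genes) the shares were 3.08%, 38.7% and 63.1%, and in the mean of both (19746 genes) 21.5%, 60% and 80.3%. For Flt3L Panc02 against Panc02 tumours they were 7.94%, 25.4% and 48.4% in asGM1-negative (19754 genes) and 7.81%, 28.1% and 66.1% in asGM1-positive cells (19723 genes). False calls were at most 5.95% in any comparison. For the interaction (19751 genes) recovery was 0, 12.5% and 53% with 4.08% false calls.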

Results

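Messenger RNA was sequenced from CD8+ T cells that had infiltrated tumours of wild-type C57BL/6J mice. The tumours grew from Panc02, a mouse pancreatic cancer cell line, or from Panc02 cells made to express Flt3L, a growth factor for dendritic cells. Cells were sorted as DAPI-negative, CD45.2+ and CD8+, and divided by asialo-GM1 (asGM1), a glycosphingolipid of the cell surface. No T cell receptor marker is named among the sort markers. The 4 groups (asGM1-negative or asGM1-positive cells, from Panc02 or Flt3L Panc02 tumours) held 3 libraries each. Library totals lay between 98663008 and 102896605 counts, and 20411 genes passed the filter on low counts. Rank correlations across genes were 0.973 to 0.983 between libraries of 1 group and 0.942 to 0.978 between groups. The labels do not say that replicates came from separate mice or tumours, so the p-values below measure the spread between these samples only.

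**Figure D1:**
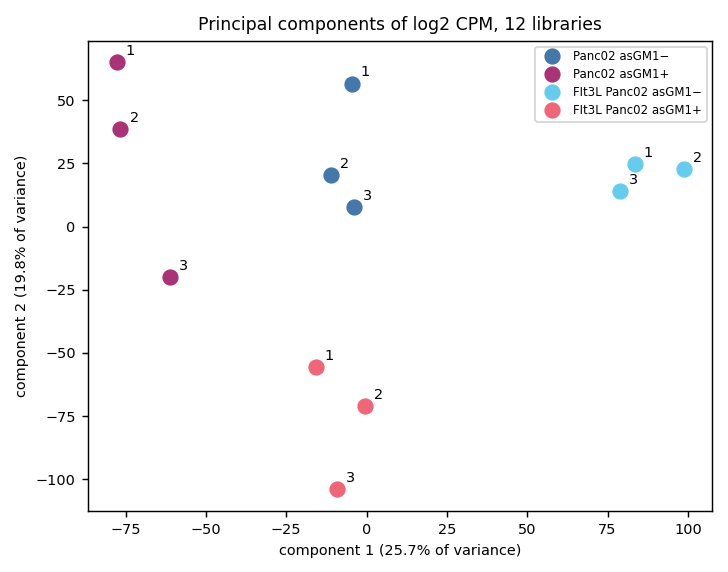
Principal component scores of the 12 libraries from log2 CPM, with component 1 (25.7% of the variance) on the horizontal and component 2 (19.8%) on the vertical axis. Each point is 1 library, coloured by group and marked with its replicate number, and the 3 asGM1-negative libraries from Flt3L Panc02 tumours lie furthest to the right, at 78.8 to 98.8 on component 1.

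Both gates held abundant Cd8a and Cd8b1, which encode the chains of the CD8 receptor. Cd8a lay between 1569 and 2562 CPM in the 12 libraries. In Flt3L Panc02 tumours Cd8b1 and the T cell gene Cd3e were called higher in asGM1-positive than in asGM1-negative cells. Those calls ended in 4 and 5 of the 6 runs that left out 1 library. B4galnt1 and B3galt4, which encode enzymes of asGM1 synthesis, were not called between the gates. In Panc02 tumours the log2 fold change from asGM1-negative to asGM1-positive cells was -0.32 ± 0.12 (SE) for B4galnt1 and -0.17 ± 0.16 for B3galt4 (edgeR adjusted p = 0.387 and 0.845). In Flt3L Panc02 tumours it was 0.41 ± 0.12 and 0.26 ± 0.16 (edgeR adjusted p = 0.0626 and 0.334). Of 19 genes for asGM1 and related glycosphingolipid enzymes, 1 was lower in asGM1-positive cells of Panc02 tumours, 0 higher and 18 not called, against 4 lower adjusted over the list alone (list adjusted p = 0.0447, and adjusted p = 0.276 with an estimated correlation). That list's adjusted p was 0.0932 without asGM1-negative replicate 3, and 0.083 and 0.266 without asGM1-positive replicates 2 and 3. In Flt3L Panc02 tumours 1 was higher, 3 lower and 15 not called, against 4 higher and 4 lower adjusted over the list alone (list adjusted p = 0.987), and B3galnt1, an enzyme of globoside synthesis, was lower by a log2 fold change of -2.74 ± 0.49. Flt3l transcripts of the sorted cells were not called between tumour types, with log2 fold changes of 0.22 ± 0.15 in asGM1-negative and 0.31 ± 0.15 in asGM1-positive cells (edgeR adjusted p = 0.458 and 0.222).

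The comparison of gates within a tumour type asks what distinguishes CD8+ T cells that carry asGM1. In Panc02 tumours, asGM1-positive cells held fewer transcripts of genes for lymph node homing, tissue exit and the naive or stem-like state than asGM1-negative cells. S1pr1, a receptor for leaving tissues, averaged 35.5 ± 5.41 CPM (SD, n = 3) in asGM1-negative and 5.39 ± 0.83 CPM (n = 3) in asGM1-positive libraries, a log2 fold change of -2.72 ± 0.22 (SE). Tcf7, a transcription factor of naive and memory T cells, was lower by -2.05 ± 0.24 on the same scale, and Ccr7, the chemokine receptor for lymph node entry, by -1.85 ± 0.21. Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were between 0.000223 and 0.00148. Of 26 naive and stem-like genes measured, 9 were lower, 0 higher and 17 not called over all genes, against 16 lower when adjusted over the list alone (list adjusted p = 6.61e-33, and 0.000415 with an estimated correlation). Of 25 chemokine and trafficking receptors, 10 were lower, 0 higher and 15 not called, against 12 lower and 2 higher adjusted over the list alone (list adjusted p = 2.16e-30, and 4.13e-05 with an estimated correlation). Il2, the T cell growth factor gene, had a log2 fold change of -2.26 ± 0.32, and Itgb7, an integrin chain of gut homing and residence, of -1.73 ± 0.15. St8sia1, a sialyltransferase that acts on related gangliosides, had -2.03 ± 0.26.

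The same asGM1-negative libraries from Panc02 tumours held more transcripts of plasmacytoid dendritic cells and of CD4 and regulatory T cells, and of some gamma delta T cell genes. Siglech, a surface receptor of plasmacytoid dendritic cells, averaged 51.2 ± 16.5 CPM (SD, n = 3) in asGM1-negative and 1.65 ± 1.51 CPM (n = 3) in asGM1-positive libraries, a call that ended with a fit to these 6 libraries alone (edgeR adjusted p = 0.0917) and without both libraries numbered 1 (0.0872). Ly6d had a log2 fold change of -5.55 ± 0.46 (SE) and Ccr9 of -5.08 ± 0.69. Of 18 plasmacytoid dendritic cell genes, 11 were lower in asGM1-positive cells, 0 higher and 7 not called, against 13 lower adjusted over the list alone (list adjusted p = 4.55e-47, and 0.000388 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, had a log2 fold change of -2.96 ± 0.31 and Cd4 of -1.31 ± 0.17. The list of CD4 and regulatory T cell genes held 5 lower, 0 higher and 10 not called of 15 measured, against 9 lower adjusted over the list alone (list adjusted p = 1.81e-14, and 0.000388 with an estimated correlation). Among 13 gamma delta and innate-like T cell genes, 5 were lower, 0 higher and 8 not called, against 9 lower and 1 higher adjusted over the list alone (list adjusted p = 6.08e-14, and 0.0116 with an estimated correlation). These included Trgc1, a gamma chain constant segment, at -2.17 ± 0.21, and Blk, a Src-family kinase, at -4.50 ± 0.53, although the summed list stood at 139 ± 17.2 CPM (SD) in asGM1-negative and 153.2 ± 12.5 CPM in asGM1-positive libraries.

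Among the genes called in Panc02 tumours, few were higher in asGM1-positive cells. Klhl30 rose from 3.22 ± 0.827 to 12 ± 1.8 CPM (SD, n = 3 each), a log2 fold change of 1.91 ± 0.21 (SE). Fcer1g, the signalling adaptor of Fc receptors and some NK receptors, was higher by 1.18 ± 0.16. Fcer1g is also a gene of myeloid cells, and 26 macrophage and monocyte genes had a median log2 fold change of 0.95, none of them called over all genes or adjusted over the list alone (list adjusted p = 2.74e-09, and adjusted p = 0.24 with an estimated correlation). Summed, they stood at 3918, 3396 and 2718 CPM in asGM1-negative and 8307, 5583 and 2741 CPM in asGM1-positive replicates 1, 2 and 3. The list tests of neutrophils and fibroblasts also pointed up (list adjusted p = 4.41e-05 and 0.000485, and adjusted p = 0.276 and 0.3 with an estimated correlation), that of fibroblasts with an adjusted p of 0.0612 without asGM1-positive replicate 2. None of the 16 neutrophil and 18 fibroblast genes was called over all genes, against 9 neutrophil genes higher and 1 lower adjusted over the list alone. Summed neutrophil genes stood at 202.1 ± 70.1 CPM (SD) in asGM1-negative and 188.8 ± 51.9 CPM in asGM1-positive libraries. Of 25 cytotoxic granule and effector genes, 0 were called by edgeR in either direction, over all genes or adjusted over the list alone (list adjusted p = 0.848). Gzmb was at 0.53 ± 0.55, Prf1 at 0.02 ± 0.38 and Pdcd1, the gene of PD-1, at 0.09 ± 0.18. Gzmb stood at 868, 3496 and 2880 CPM in asGM1-negative replicates 1, 2 and 3. In asGM1-positive replicates it stood at 1724, 4780 and 3974 CPM, higher at each number. Prf1 was lower in asGM1-positive cells at number 3, at 1039 against 1090 CPM. The model does not pair libraries by number. Over all genes edgeR called 182, of which 10 were higher and 172 lower in asGM1-positive cells, and 2040 had an unadjusted p under 0.05. The number higher was 77 of 226 without asGM1-positive replicate 3, 135 of 598 by DESeq2 and 286 of 831 by limma-voom. The count was 109 without asGM1-negative replicate 1, 112 without asGM1-negative replicate 2, 94 without asGM1-positive replicate 2 and 118 with a fit to these 6 libraries alone. Without both libraries numbered 1, chosen after the data were seen because their macrophage and MHC class II transcripts were high, it was 107 and the adjusted p of Fcer1g was 0.055.

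**Figure D2:**
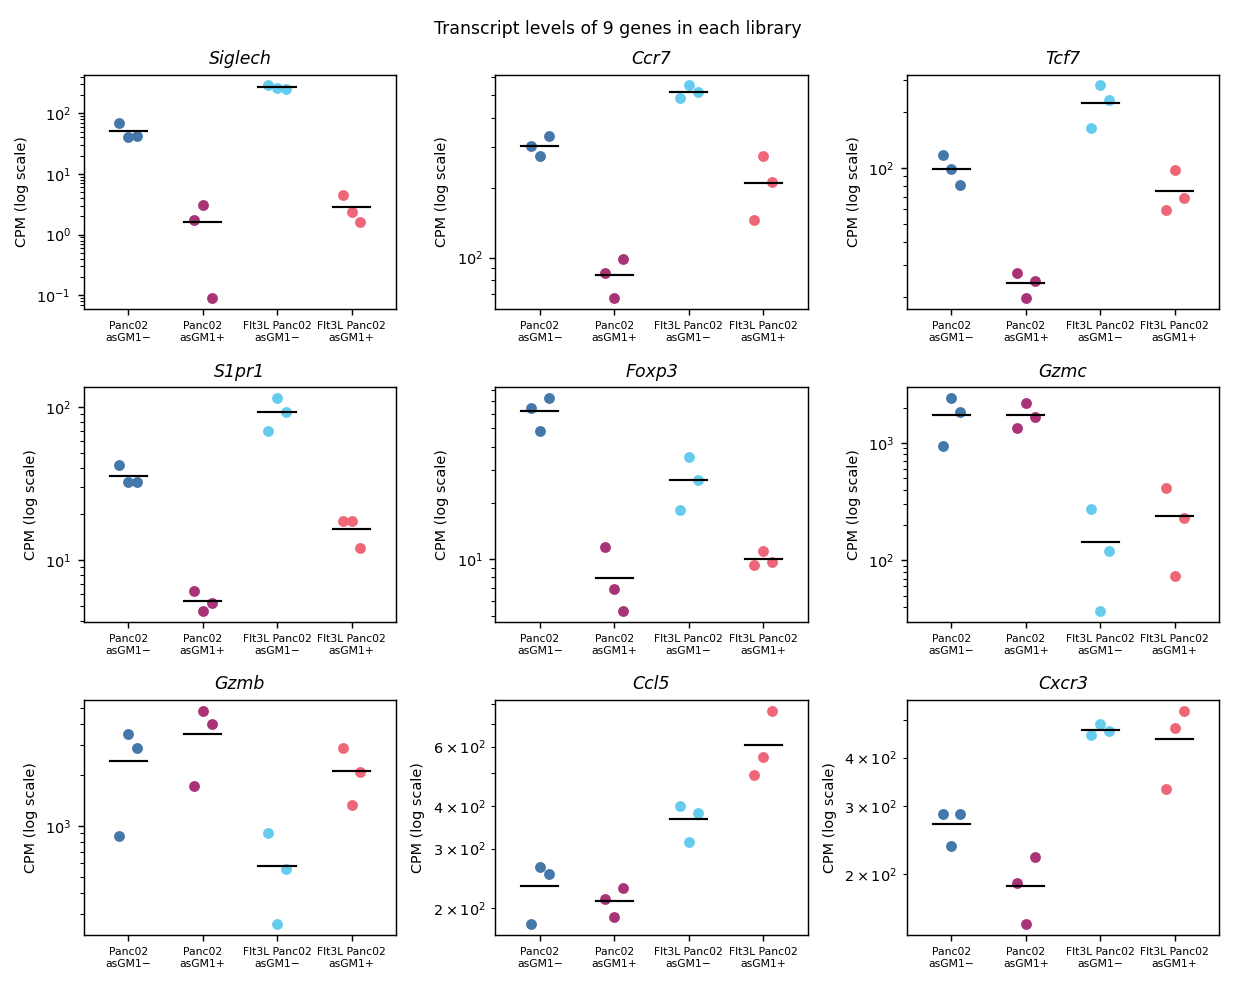
CPM on a log axis of 9 genes in the 12 libraries, 1 panel per gene, with each point 1 library and each line the group mean. Siglech, Ccr7, Tcf7, S1pr1 and Foxp3 sit higher in the asGM1-negative libraries of both tumour types, with S1pr1 at 35.5 and 92.1 CPM there against 5.39 and 16 CPM in asGM1-positive libraries.

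In Flt3L Panc02 tumours, asGM1-positive cells again held fewer transcripts of naive and stem-like genes and of most called trafficking receptors, with a mixed change in tissue residence genes. Called cell cycle genes were higher, although that list was not called with an estimated correlation. S1pr1 averaged 92.1 ± 22.2 CPM (SD, n = 3) in asGM1-negative and 16 ± 3.45 CPM (n = 3) in asGM1-positive libraries, a log2 fold change of -2.52 ± 0.22 (SE). Tcf7 was at -1.58 ± 0.23, and Il7r, the receptor chain for the survival cytokine IL-7, at -1.47 ± 0.17. Of 26 naive and stem-like genes, 17 were lower, 0 higher and 9 not called, against 19 lower adjusted over the list alone (list adjusted p = 3.46e-20, and 0.00501 with an estimated correlation). Of 25 chemokine and trafficking receptors, 10 were lower, 2 higher and 13 not called, against 10 lower and 5 higher adjusted over the list alone (list adjusted p = 2.09e-05, and 0.0174 with an estimated correlation). Adgrg1, an adhesion receptor of cytotoxic lymphocytes, was higher by 1.82 ± 0.18, from 14 ± 3.4 to 49.4 ± 8.22 CPM (SD, n = 3 each). Itga1, the collagen-binding integrin chain CD49a, was higher by 1.17 ± 0.21, and Cxcr6, a receptor of tissue-resident T cells, by 0.78 ± 0.13, while Itgae, the residence integrin chain CD103, was lower by a log2 fold change of -1.91 ± 0.34. Itgae was also called lower in asGM1-positive cells of Panc02 tumours. That call ended in 1 of 6 runs that left out 1 library and with a fit to the compared libraries alone. In the tissue residence list of Flt3L Panc02 tumours 5 genes were higher, 4 lower and 14 not called, against 7 higher and 6 lower adjusted over the list alone (list adjusted p = 0.557). Pdcd1 was higher by 0.88 ± 0.18 with an edgeR adjusted p of 0.0129, and its adjusted p was 0.062 without asGM1-negative replicate 2.

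Dividing-cell genes were higher in the asGM1-positive cells of Flt3L Panc02 tumours, among them Bub1 by a log2 fold change of 0.78 ± 0.11 (SE, n = 3 against 3) and Ccnb1 by 0.71 ± 0.11. Of 40 cell cycle genes, 18 were higher, 0 lower and 22 not called, against 32 higher adjusted over the list alone (list adjusted p = 6.78e-20). The adjusted p was 0.127 with an estimated correlation. Mki67 was at 0.02 ± 0.15. Summed cell cycle genes also stood higher in asGM1-positive libraries of Panc02 tumours, at 9084 ± 552 against 8022 ± 199 CPM (SD). In Flt3L Panc02 tumours they stood at 7982 ± 921 against 5597 ± 671 CPM. Type I interferon response genes were lower, with 22 of 44 lower, 0 higher and 22 not called, against 33 lower adjusted over the list alone (list adjusted p = 7.1e-14, and adjusted p = 0.052 with an estimated correlation). Irf7, a regulator of that response, was at -0.91 ± 0.12. The part of plasmacytoid dendritic cell RNA in this list was not tested, here or in the mean of both tumour types. Of 25 cytotoxic granule and effector genes, 4 were higher, 0 lower and 21 not called, against 5 higher adjusted over the list alone (list adjusted p = 0.000114, and adjusted p = 0.337 with an estimated correlation). Ctsd, a lysosomal protease, was higher by 0.83 ± 0.11, while Gzmb at 1.87 ± 0.57 did not pass (edgeR adjusted p = 0.0649). Gzmb stood at 906.1, 262.3 and 556.3 CPM in asGM1-negative replicates 1, 2 and 3. In asGM1-positive replicates it stood at 2876, 1331 and 2085 CPM. Summed T cell identity genes stood higher too, at 21070 ± 2960 CPM (SD) in asGM1-positive and 16710 ± 835 CPM in asGM1-negative libraries. In Panc02 tumours they stood at 14620 ± 1490 and 16640 ± 1790 CPM, the other way.

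Transcripts of other cell types moved with the gates here too. Siglech averaged 268 ± 19.2 CPM (SD, n = 3) in asGM1-negative and 2.83 ± 1.54 CPM (n = 3) in asGM1-positive libraries of Flt3L Panc02 tumours. Of 18 plasmacytoid dendritic cell genes, 14 were lower in asGM1-positive cells, 0 higher and 4 not called, against 16 lower and 1 higher adjusted over the list alone (list adjusted p = 1.43e-35, and 0.00501 with an estimated correlation). Of 15 CD4 and regulatory T cell genes, 6 were lower, 0 higher and 9 not called, and 6 were lower adjusted over the list alone (list adjusted p = 0.000491, and 0.0286 with an estimated correlation). The summed list differed little, at 1185 ± 115 CPM (SD) in asGM1-negative and 1148 ± 98.5 CPM in asGM1-positive libraries. Cd4 was at -2.56 ± 0.18 (SE). Of 13 gamma delta and innate-like genes, 8 were lower, 0 higher and 5 not called, against 10 lower adjusted over the list alone (list adjusted p = 3.58e-13, and 0.0214 with an estimated correlation). Clec10a, a lectin of dendritic cells and macrophages, was at -3.21 ± 0.21, and other dendritic cell genes held 9 lower, 0 higher and 7 not called of 16, with 9 lower adjusted over the list alone (list adjusted p = 4.78e-11, and adjusted p = 0.0712 with an estimated correlation). Over all genes edgeR called 1754, with 565 higher and 1189 lower in asGM1-positive cells. The number higher was 1309 of 3215 by DESeq2 and 1163 of 2805 by limma-voom. The count was 768 and 1077 without asGM1-negative replicates 2 and 3, and 1125, 1087 and 985 without asGM1-positive replicates 1, 2 and 3. A fit to these 6 libraries alone called 1094, of which 195 were higher.

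Among called genes, the gate effects of the tumour types, which share no library, ran largely the same way. Of the 182 genes called in Panc02 tumours, 176 (96.7%) had the same sign in Flt3L Panc02 tumours. Among genes called in both, 144 were lower in both, where independent lists would share 10, and 6 were higher in both, where they would share 0.277, and 0 went in opposite directions. The log2 fold changes had a Pearson correlation of 0.297 across 20411 genes, which are not independent replicates, and of 0.564 with a stricter filter on low counts, and their Spearman correlation was 0.125. The mean of both effects called 1263 genes by edgeR, 343 higher and 920 lower in asGM1-positive cells (n = 6 against 6). That count was 826 without asGM1-positive replicate 2 of Panc02 tumours and 809 without asGM1-negative replicate 2 of Flt3L Panc02 tumours. Klhl30 was higher by a mean log2 fold change of 1.70 ± 0.15 (SE), and St8sia1 lower by a mean log2 fold change of -2.27 ± 0.19. In this mean, 18 of 44 type I interferon response genes were lower, 0 higher and 26 not called, against 30 lower adjusted over the list alone (list adjusted p = 1.89e-16, and 0.0324 with an estimated correlation).

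**Figure D3:**
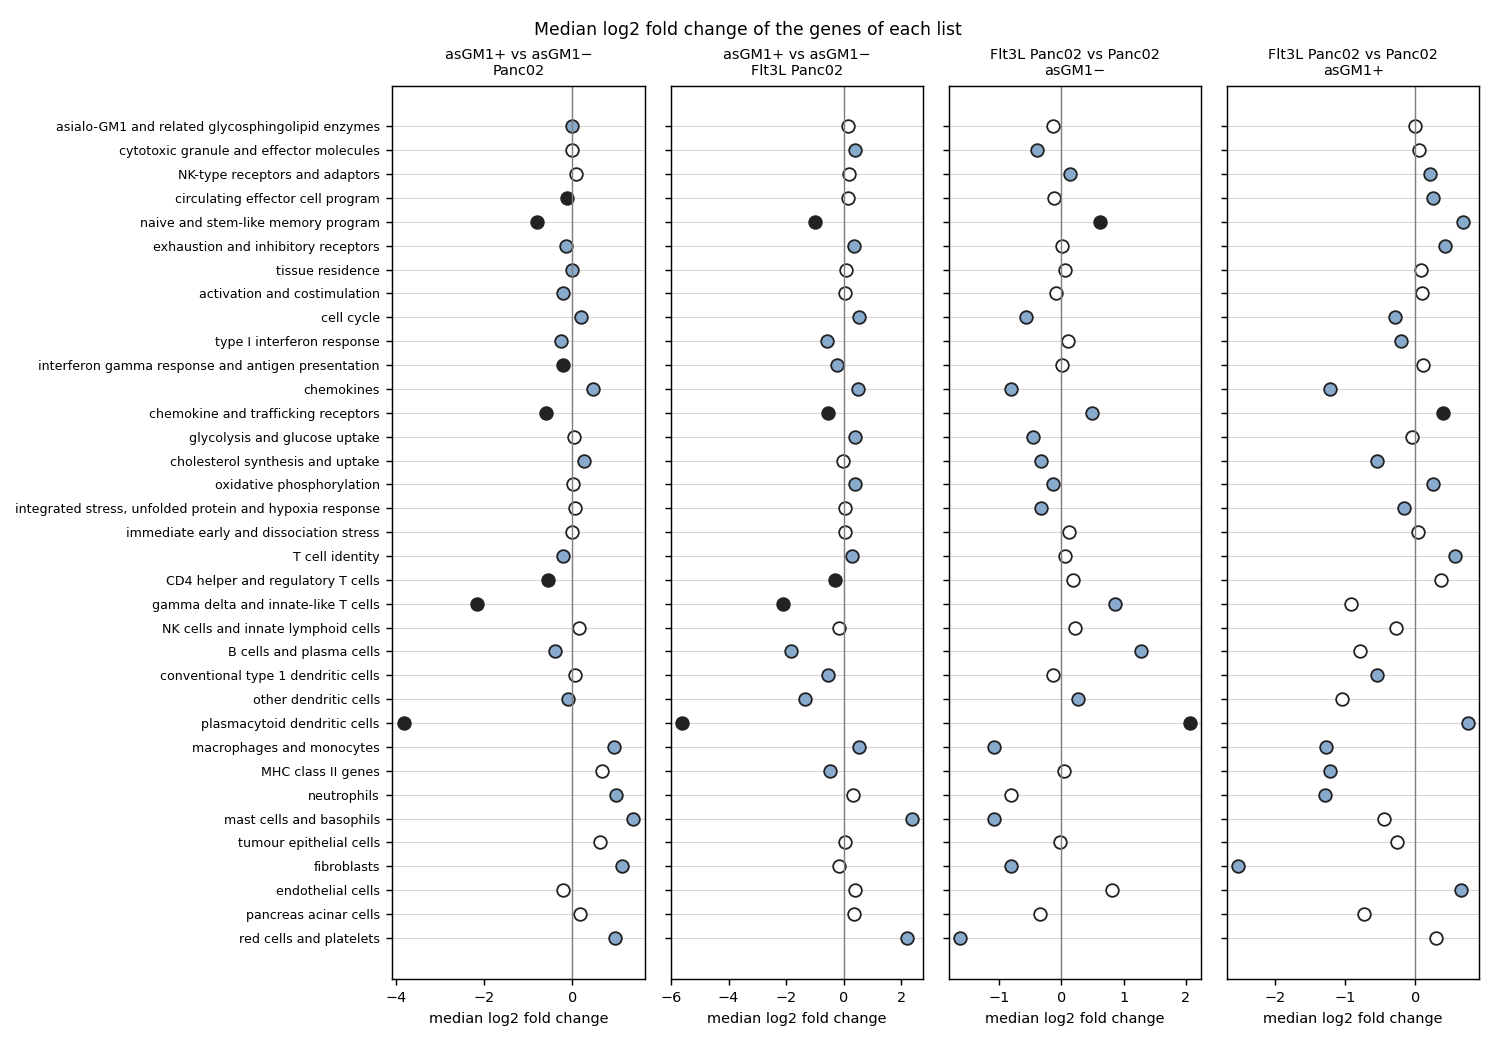
Median log2 fold change of the gene lists, 1 panel per comparison with its own horizontal scale. Each point is 1 list, black where its call held with the preset and the estimated correlation, blue where it held with the preset correlation only and white where it was not called, and the plasmacytoid dendritic cell list lies at -3.82 in Panc02 and -5.62 in Flt3L Panc02 tumours for asGM1-positive against asGM1-negative cells.

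The comparison of tumour types within a gate asks how the cells differ when the tumour expresses Flt3L. In asGM1-negative cells, Klra1, Klra6, Klra7 and Klra9, which encode Ly49 receptors of NK cells and some T cells, rose in Flt3L Panc02 tumours, while granzymes C to F and cell cycle genes fell. Klra6 rose from 6.94 ± 1.01 to 25.3 ± 4.58 CPM (SD, n = 3 each), a log2 fold change of 1.87 ± 0.18 (SE), and Klra7 rose by 1.78 ± 0.19, while Klra2 had a log2 fold change of -1.81 ± 0.39. Of 29 genes for NK-type receptors and adaptors, 5 rose, 0 fell and 24 were not called, against 9 higher and 5 lower adjusted over the list alone (list adjusted p = 0.00891, and adjusted p = 0.413 with an estimated correlation). That list's adjusted p was 0.293 without Panc02 replicate 1, 0.118 without Flt3L Panc02 replicate 1 and 0.29 without both Panc02 libraries numbered 1. Gzmc, a granzyme of activated cytotoxic cells, averaged 1740 ± 739 CPM in Panc02 and 145 ± 121 CPM in Flt3L Panc02 tumours, a log2 fold change of -3.59 ± 0.74 (edgeR adjusted p = 0.0257). Gzmd was at -3.67 ± 0.75, Gzme at -3.41 ± 0.77 and Gzmf at -3.49 ± 0.80. Each granzyme call ended without any 1 of 4 libraries. Without Panc02 replicates 2 or 3 the adjusted p of Gzmc was 0.0949 and 0.068, and without Flt3L Panc02 replicates 2 or 3 it was 0.0777 and 0.0909. Without the same 4 libraries it was 0.0952, 0.0741, 0.124 and 0.0874 for Gzmd, 0.124, 0.102, 0.141 and 0.108 for Gzme, and 0.127, 0.103, 0.104 and 0.108 for Gzmf. With no filter on low counts it was 0.0659 for Gzme and 0.0703 for Gzmf, and a fit to these 6 libraries alone gave 0.0539 for Gzmf. In the cytotoxic list 4 genes were lower, 0 higher and 21 not called, against 7 lower adjusted over the list alone (list adjusted p = 1.1e-06, and adjusted p = 0.293 with an estimated correlation).

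Of 40 cell cycle genes in the asGM1-negative cells, 18 fell in Flt3L Panc02 tumours, 0 rose and 22 were not called, against 37 lower adjusted over the list alone (list adjusted p = 2.74e-31, and adjusted p = 0.0937 with an estimated correlation). Bub1 fell by a log2 fold change of -1.03 ± 0.11 (SE, n = 3 against 3) and Ccnb1 by -0.75 ± 0.11. Naive and stem-like genes rose, with 9 of 26 higher, 0 lower and 17 not called, against 16 higher adjusted over the list alone (list adjusted p = 9.4e-15, and 0.0303 with an estimated correlation). Lef1 rose by 1.05 ± 0.17 and Bcl2, a survival factor, by 0.82 ± 0.12. The adjusted p of Lef1 was 0.0536 without Flt3L Panc02 replicate 2 and that of Bcl2 0.0517 without Panc02 replicate 2. Plasmacytoid dendritic cell genes rose beside them, with 9 of 18 higher, 0 lower and 9 not called, against 15 higher adjusted over the list alone (list adjusted p = 6.39e-15, and 0.0374 with an estimated correlation). Upb1 of that list rose by 2.45 ± 0.27, and Clec10a by 1.67 ± 0.19. Plaur, the urokinase receptor, rose from 15.5 ± 1.96 to 64.9 ± 6.15 CPM (SD). Acta2, smooth muscle actin, fell by -3.36 ± 0.48 and Krt18, a keratin, by -2.43 ± 0.37, while the list of tumour epithelial cells held 3 lower, 1 higher and 15 not called of 19, with 4 lower and 1 higher adjusted over the list alone (list adjusted p = 0.266). The fibroblast list held 4 lower, 0 higher and 14 not called of 18, with 4 lower adjusted over the list alone (list adjusted p = 0.00233, and adjusted p = 0.447 with an estimated correlation). That list's adjusted p was 0.074 without Flt3L Panc02 replicate 1. Over all genes edgeR called 756, 380 higher and 376 lower. The count was 400, 94 and 170 without Panc02 replicates 1, 2 and 3, 121 and 298 without Flt3L Panc02 replicates 2 and 3, 481 without both Panc02 libraries numbered 1, and 390 with no filter on low counts.

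In asGM1-positive cells, most called chemokine and trafficking receptors and most called naive-state genes rose in Flt3L Panc02 tumours. The naive-state list was not called with an estimated correlation. Of 25 chemokine and trafficking receptors, 8 rose, 1 fell and 16 were not called, against 11 higher and 2 lower adjusted over the list alone (list adjusted p = 4.87e-08, and 0.0086 with an estimated correlation). Cxcr4, a retention receptor, rose by a log2 fold change of 2.12 ± 0.31 (SE), from 2.21 ± 0.398 to 9.6 ± 2 CPM (SD, n = 3 each). Cxcr3, a receptor for interferon-induced chemokines, rose by 1.26 ± 0.18, and Ccl5, a chemokine made by effector T cells, by 1.53 ± 0.19. Of 26 naive and stem-like genes, 10 rose, 2 fell and 14 were not called, against 12 higher and 3 lower adjusted over the list alone (list adjusted p = 1.06e-08, and adjusted p = 0.0724 with an estimated correlation). Tcf7 rose by 1.66 ± 0.23, S1pr1 by 1.57 ± 0.22 and Ccr7 by 1.32 ± 0.21. Klra6 rose by 1.84 ± 0.18 and Klra7 by 1.83 ± 0.19. Of 18 plasmacytoid dendritic cell genes, 2 were higher, 0 lower and 16 not called, against 4 higher and 2 lower adjusted over the list alone (list adjusted p = 0.00594, and adjusted p = 0.319 with an estimated correlation). That list's adjusted p was 0.105 without Panc02 replicate 3 and 0.0851 without Flt3L Panc02 replicate 1. Cd160, an inhibitory receptor, rose by 1.02 ± 0.16. In the exhaustion and inhibitory receptor list 8 rose, 0 fell and 20 were not called, against 12 higher adjusted over the list alone (list adjusted p = 3.08e-07, and adjusted p = 0.147 with an estimated correlation). T cell identity genes rose as well, with 7 of 20 higher, 0 lower and 13 not called, against 16 higher adjusted over the list alone (list adjusted p = 6.35e-13, and adjusted p = 0.148 with an estimated correlation).

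Several macrophage and fibroblast genes fell in the asGM1-positive cells of Flt3L Panc02 tumours. Spp1, osteopontin, averaged 774 ± 326 CPM (SD, n = 3) in Panc02 and 191 ± 47.6 CPM (n = 3) in Flt3L Panc02 tumours, a log2 fold change of -2.02 ± 0.30 (SE). Fn1, fibronectin, fell by -2.95 ± 0.42, Acta2 by -4.54 ± 0.51 and Krt18 by -3.00 ± 0.38 on the same scale. Of 18 fibroblast genes, 6 fell, 0 rose and 12 were not called, against 11 lower adjusted over the list alone (list adjusted p = 8.2e-07, and adjusted p = 0.284 with an estimated correlation). Of 19 tumour epithelial genes, 4 fell, 1 rose and 14 were not called, against 5 lower and 1 higher adjusted over the list alone (list adjusted p = 0.0772). Of 26 macrophage and monocyte genes, 10 fell, 0 rose and 16 were not called, against 22 lower and 1 higher adjusted over the list alone (list adjusted p = 3.99e-10, and adjusted p = 0.284 with an estimated correlation). The summed macrophage list was at 8307, 5583 and 2741 CPM in Panc02 replicates 1, 2 and 3. Of 44 type I interferon response genes, 9 fell, 0 rose and 35 were not called, against 15 lower and 3 higher adjusted over the list alone (list adjusted p = 0.000113, and adjusted p = 0.306 with an estimated correlation), with Ifi44 at -2.38 ± 0.35. Cholesterol synthesis and uptake genes held 8 lower, 1 higher and 18 not called of 27, against 21 lower and 2 higher adjusted over the list alone (list adjusted p = 2.15e-08, and adjusted p = 0.147 with an estimated correlation). Gzmd fell by -3.59 ± 0.75 (edgeR adjusted p = 0.021), and its adjusted p was 0.0715 without Panc02 replicate 2, and 0.0694 and 0.0835 without Flt3L Panc02 replicates 2 and 3. Gzmf at -2.63 ± 0.77 was not called (edgeR adjusted p = 0.0663). Over all genes edgeR called 1276, 418 higher and 858 lower. The count was 414 and 305 without Panc02 replicates 1 and 2, 215 and 263 without Flt3L Panc02 replicates 2 and 3, 402 without both Panc02 libraries numbered 1, and 691 with no filter on low counts. A fit to these 6 libraries alone called 1 gene, with 4515 at an unadjusted p under 0.05 and adjusted p-values from 0.0507 to 0.112 for the 96 called genes that the naming rule selected, where DESeq2 and limma-voom on all 12 libraries called 2979 and 3120.

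The interaction asks whether the difference between gates depends on the tumour. It called 75 genes by edgeR, 7 higher and 68 lower, where lower means a more negative difference between asGM1-positive and asGM1-negative cells in Flt3L Panc02 tumours. The number higher was 233 of 862 by DESeq2 and 263 of 786 by limma-voom. Plaur had log2 fold changes of -0.49 ± 0.23 (SE, n = 3 against 3) in Panc02 and -3.93 ± 0.25 in Flt3L Panc02 tumours, an interaction of -3.44 ± 0.33 (edgeR adjusted p = 0.00553). Slpi, a protease inhibitor of myeloid and epithelial cells, had -0.11 ± 0.22 and -2.96 ± 0.24, an interaction of -2.85 ± 0.32 (edgeR adjusted p = 0.014). The adjusted p of Slpi was 0.0739 and 0.0513 without asGM1-negative replicates 2 and 3 of Panc02 tumours and 0.0538 without asGM1-negative replicate 1 of Flt3L Panc02 tumours. Of the lists, 3 of 18 plasmacytoid dendritic cell genes were lower by the interaction, 0 higher and 15 not called, with 3 lower and 1 higher adjusted over the list alone (list adjusted p = 0.000471, and adjusted p = 0.408 with an estimated correlation). The part of other cells' RNA in the called interactions was not tested. Of the 15 interaction genes examined by name, Plaur alone was called whichever library was left out. The count was 27, 1 and 2 without asGM1-negative replicates 1, 2 and 3 of Panc02 tumours and 43, 3 and 257 without asGM1-positive replicates 1, 2 and 3. In Flt3L Panc02 tumours it was 1, 4 and 39 without asGM1-negative replicates 1, 2 and 3 and 41, 6 and 4 without asGM1-positive replicates 1, 2 and 3.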

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

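The splits of libraries were planned, and no test in this part was chosen after its result was seen. The difference between asGM1-positive and asGM1-negative cells was itself different between tumour types for 75 genes by edgeR's interaction test. Among 100 splits that exchanged libraries between gates within each tumour type, 3 gave at least 75 genes, the labelled split included. Such exchanges also take away the gate effect, so they do not decide whether chance can be excluded for the interaction. The highest other split called 826, several times the labelled count. It kept the gate labels of the Flt3L Panc02 libraries and exchanged those of Panc02 libraries, so it still holds the gate effect of 1 tumour type and points to that structure of the samples.

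Higher by the interaction were Adap1 (log2 difference 1.31), Cdkn2c (1.14) and Anxa6 (0.86). Lower were Plaur (-3.44), P2ry13 (-3.56), Slpi (-2.85), Tcf4 (-3.01), Nucb2 (-2.67), Upb1 (-2.36), Tyrobp (-2.27), Lair1 (-2.24), Kcnq1ot1 (-1.64) and Bcl2 (-1.17). Upb1 is a listed plasmacytoid dendritic cell gene. In asGM1-negative cells that list summed to 755.6 CPM in Panc02 and 1608 CPM in Flt3L Panc02 tumours. In asGM1-positive cells it summed to 477.5 and 523.7 CPM. More RNA of other cells in the asGM1-negative gate can by itself make an interaction negative, and its part here was not tested. The fitted interactions of Hbb-bs (6.92) and Hbb-bt (6.93) are no bounds, because both lay under the floor of 0.082 CPM in asGM1-negative cells of Flt3L Panc02 tumours, at 0.0189 and 0.0063 CPM. Plaur alone of these 15 genes kept its call in all runs that left out 1 library.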

How the results depend on the processing

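Counts scaled to fragments, the run without both Panc02 libraries numbered 1 and the count without genes of other cell types were chosen after seeing the data. In the order gate effect in Panc02, in Flt3L Panc02, their mean, tumour effect in asGM1-negative, in asGM1-positive cells, and interaction, DESeq2 called 598, 3215, 2342, 2207, 2979 and 862 genes and limma-voom 831, 2805, 2528, 3536, 3120 and 786, against 182, 1754, 1263, 756, 1276 and 75 by edgeR. With no filter on low counts the last 3 counts were 390, 691 and 40. A stricter filter gave 137 for the interaction and raised the correlation of gate effects to 0.564. Fits to the compared libraries alone gave 118 and 1094 for the gates, and 836 and 1 for the tumour effects in asGM1-negative and asGM1-positive cells. Without both Panc02 libraries numbered 1 the counts were 107 for the gate in Panc02, 481 and 402 for the tumour effects and 27 for the interaction. Leaving out 1 library in turn gave 94 to 226, 768 to 1942, 809 to 1589, 94 to 959, 215 to 1737 and 1 to 257. The cause was not tested for the choice of tool and filter. DESeq2 size factors, upper quartile factors and counts scaled to fragments moved no count by over 1.5 times, and no called gene selected by the naming rule and no called list reversed its direction in these runs. Genes and lists that were not called were not followed.

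Each library correlated best with its own number across gates, with correlations of 0.284, 0.095 and 0.166 in Panc02 and 0.054, 0.104 and 0.022 in Flt3L Panc02 tumours. Several of these were near 0 and the labels do not state a pairing, so the main model took none. If the numbers do mark shared tumours, that model counts shared variation as error. Gate differences can then be missed, and a gene not called between gates is no evidence of equal levels. With the replicate number as a block the counts were 248, 2104, 1602, 736, 1490 and 204. Among the tumour effects in asGM1-negative cells, the block also ended the calls of Gzme, Gzmf and Foxp3. At this depth and n, 7.94% of simulated 1.5-fold changes were recovered in the Panc02 gate comparison, so smaller changes can be missed.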

Other observations

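The tests of naive genes against plasmacytoid genes and of granzymes against T cell identity genes were chosen after the results were seen, as were those of the growth of excess in other T cell genes and of the summed granzymes. Red cell and mast cell transcripts were low in every library and lowest in asGM1-negative cells of Flt3L Panc02 tumours. The summed list of red cell and platelet genes averaged 0.971 ± 0.481 CPM (SD, n = 3) there and 21.2 ± 9.91 CPM (n = 3) in asGM1-positive cells of the same tumours, with 9.33 ± 4.63 and 19.1 ± 4.35 CPM in asGM1-negative and asGM1-positive cells of Panc02 tumours. Of its 9 genes, 4 were higher in asGM1-positive cells of Flt3L Panc02 tumours, 0 lower and 5 not called, against 5 higher adjusted over the list alone (list adjusted p = 1.11e-08 by camera, and adjusted p = 0.052 with an estimated correlation). Hba-a1, a haemoglobin chain, averaged 0.12 ± 0.147 and 7.51 ± 3.59 CPM in those gates. Cpa3, a protease of mast cells, averaged 0.182 ± 0.127 and 2.74 ± 0.869 CPM.

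Cd4 rose and Foxp3 fell in asGM1-negative cells. From Panc02 to Flt3L Panc02 tumours Cd4 rose from 7.59 ± 1.33 to 28.1 ± 4.68 CPM (SD, n = 3 each), a log2 fold change of 1.89 ± 0.18 (SE, edgeR adjusted p = 0.0015). Siglech, of plasmacytoid dendritic cells, rose from 51.2 to 268 CPM in the same libraries, and the excess of Cd4 over asGM1-positive cells grew by a factor of 5.14, within the plasmacytoid genes' quartiles of 4.92 to 5.82, so Cd4 is no clean marker of CD4 T cells here. Foxp3 fell from 61.8 ± 12.3 to 26.6 ± 8.4 CPM, a log2 fold change of -1.22 ± 0.29 (edgeR adjusted p = 0.0435), a call that ended without any 1 of the 6 libraries. Its adjusted p was 0.0986, 0.0887 and 0.138 without Panc02 replicates 1, 2 and 3, 0.0797, 0.067 and 0.116 without Flt3L Panc02 replicates 1, 2 and 3, and 0.074 with no filter on low counts.

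For comparisons of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05, and 1 split, the labelled one, gave as many genes in each. The labelled and highest other counts were 182 and 1 for the gates in Panc02, 1754 and 0 in Flt3L Panc02, 756 and 1 for the tumours in asGM1-negative and 1276 and 1 in asGM1-positive cells. For the mean gate effect 1 of 100 splits, the labelled one, reached 1263 genes and the highest other 660. That share is under 0.05, so the labelled grouping stands out among these splits. Splits that reverse all gate labels of 1 tumour type were not among them. Replicates are not known to come from separate mice or tumours, so the share covers these libraries only.

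Plasmacytoid dendritic cell transcripts were higher in asGM1-negative libraries, from a gate on CD45.2 and CD8 that names no T cell receptor. Across those 6 libraries, centred within tumour type, the 10 listed genes lower in both asGM1-positive groups had a mean pairwise correlation of 0.467, above 99% of 1000 equal sets from 134 other such genes (median 0.123, 95th percentile 0.365). A candidate explanation is plasmacytoid dendritic cells in the asGM1-negative gate, with Siglech at 268 CPM and Ly6d at 149 CPM in Flt3L Panc02 tumours. Of the 18 listed genes, 5 are in another list and 7 exceeded 5 CPM in both asGM1-positive groups. Expression of these genes by CD8+ T cells themselves was not tested and stays open.

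Naive and stem-like genes were lower in asGM1-positive libraries. If RNA of plasmacytoid dendritic cells were the cause, the excess in asGM1-negative cells would grow from Panc02 to Flt3L Panc02 tumours by 1 factor for both sets. It grew by a median of 1.84 for 8 naive genes (quartiles 1.63 to 2.35) and 5.24 for 10 plasmacytoid genes (quartiles 4.92 to 5.82), which argues against that RNA as the cause. Among gamma delta genes lower in both tumour types, factors were 1.82 (Blk), 1.96 (Il23r), 1.99 (Trgc1) and 2.85 (Trgc4), so RNA of gamma delta T cells stays open, while Cd4 (5.14) and Foxp3 (0.308) give no single factor for CD4 T cells, which a sort on CD8 is meant to leave out. A difference in state between asGM1-negative and asGM1-positive CD8+ T cells was not tested and stays open.

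The fitted log2 fold changes of granzymes C to F from Panc02 to Flt3L Panc02 tumours were negative in both gates, although Gzmf was not called in asGM1-positive cells (edgeR adjusted p = 0.0663). A change in the share of other cells' RNA would move T cell genes together, but the highest granzyme log2 fold change was -2.63 in asGM1-positive cells, against a median of 0.56 for 20 T cell identity genes, and -3.41 in asGM1-negative cells against a median of 0.06. The Panc02 libraries numbered 1 held the lowest Gzmc of their groups, at 947 CPM in asGM1-negative and 1335 CPM in asGM1-positive cells. Such low levels lessen the fall, which argues against those libraries as the cause for Gzmc. Without both, the median granzyme log2 fold change was -3.89 in asGM1-negative cells, against -3.54 with all libraries. In asGM1-positive cells it was -3.38 against -3.11. With the lowest libraries removed, Gzmc was bound to fall further, so this run adds no support of its own. Reads shared among these 4 genes would leave their sum. In asGM1-positive cells it averaged 2370 ± 713 CPM (SD, n = 3) in Panc02 and 334 ± 224 CPM in Flt3L Panc02 tumours, 7.09-fold apart. In asGM1-negative cells it averaged 2370 ± 1110 and 200 ± 158 CPM, and neither gate had overlap. This argues against such sharing as the cause for Gzmc, which made up most of the sum. In asGM1-positive cells of Panc02 tumours Gzmc averaged 1720 CPM, Gzmd 71.2, Gzme 62.7 and Gzmf 515 CPM. The sum therefore cannot decide whether sharing made the falls of Gzmd, Gzme or Gzmf. Reads shared with other paralogs, and an effect of Flt3L expression in the tumour, were not tested and stay open.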
